A study of Mus musculus with 34 samples.

How the data were processed

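RNA of the cerebral cortex of C57BL/6N mouse offspring had been hybridised to 34 single-colour Applied Biosystems chemiluminescent arrays, 1 array per sample. Per the labels' protocols, breeding mice were bought at 6 weeks of age, MDMA was given by mouth at 20 mg/kg in 3 ml/kg of saline, RNA with a 28S to 18S ratio above 1.6 was kept, and 1 microgram of total RNA was transcribed into digoxigenin-labelled cRNA. The labels name sex and treatment for every sample. They call the controls non-treated, and no dose volume is recorded for them here. They give no litter, dissection day, slide or age of the offspring, and nothing says that samples of a group came from separate litters. The p-values therefore set each difference against the spread between these samples, taken as independent. If samples shared a litter, the p-values may be too small, and females and males may not be independent of each other either.

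Per the file headers, each deposited array file holds a signal intensity, a signal-to-noise ratio, a quality flag and a standard deviation for each of 33315 rows. Of these, 303 were control rows and 33012 were gene probes. On the 30.6% of gene spots that carried flag 1, the signal was equal to its own standard deviation (100% of them, within 0.011 signal units), so the lowest intensities are a floor and not a level. Per the file headers, the signal-to-noise score was deposited beside each signal, with no further step recorded. The software version and settings behind the intensities and scores are not given in the sources used here. The authors also deposited a table of log2 values. Set against the array files, its columns had a rank correlation with the signal of 1 on every array, shared a maximum of 21.16 and had medians from 12.02 to 12.56, as quantile-normalised log2 signals would, and its 36% of empty cells were the spots with a signal-to-noise ratio under 1.5 or a flag of 5000 or more, with 0 exceptions either way. Whether any further centring was applied to that table is unknown.

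For the present comparisons, spots with a flag of 5000 or more (5195 spots, 0.46%) were set to missing, signals were taken to log2 and quantile normalised over all 33012 gene probes, and control rows were left out. A probe was tested if its signal-to-noise ratio was at least 3 in a share of at least 0.5 of the arrays of at least 1 group, which left 19022 probes. A linear model with a mean for each of the 4 groups was fitted to all 34 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Contrasts were MDMA minus control in each sex, their average, their difference (the interaction), and female minus male in controls and in MDMA offspring. The correlation of the female and male effects was taken across probes, which are not independent replicates, and was set against 100 regroupings of the arrays within each sex. Array counts limit the precision of all values.

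Most probes carry identifiers of an older gene catalogue. Names were taken from a RefSeq gene table of GRCm38.p6 alone, by accession without version for 311 probes and by synonym for 5, so 316 probes had a symbol. Of these, 178 were tested, for 174 genes. The array's own genome build is not given in the sources used here, and no coordinates are printed. A gene with several tested probes was given by the probe with the highest mean signal. The rule for named genes, set before the data were examined, took for each MDMA contrast the 10 largest rises and 10 largest falls past the threshold with a symbol, and for each sex difference the 5 largest either way, along with called members of 40 gene lists, at most 4 per list. It also asked for 16 transmitter, activity, cell type and blood genes and 5 sex-linked genes whatever their test gave. Of these, 0 had a named probe among those tested. A result that this rule names for the interaction is not reported here, and none was put in its place. No list had 5 tested members (at most 2), so the planned list tests (camera and fry) gave no value. In their place, 7 groups were formed from the symbols alone, after the names were seen and before any test; 4 of them had at least 5 tested members and were tested with camera, with an inter-gene correlation of 0.01 and with an estimated one.

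Alternatives fixed before the data were examined were median centring, an offset of 50 before the logarithm, the authors' table, no filter on dim probes, a signal-to-noise ratio of at least 3 on all arrays, keeping poor-quality spots, eBayes with trend and robust, array weights, fitting the compared groups alone, a replicate block, and leaving out each array in turn. A block for slide or scan date was planned but the files gave none. Added after seeing the data were a covariate for a set of 20 arrays that shared on/off probes, fits within each set, and 2 components of the 33 spike-in control probes as covariates. The set was read from probes with a gap of at least 2 log2 units between arrays, a highest value of at least 12, and 5 or more arrays on each side. The statistics were tested on simulated data with 19022 probes, of which 100 were changed by 0.5 and 100 by 1 log2 unit. Values were drawn independently from a normal distribution at each probe's own mean and spread. Correlation between probes, the array set and the floor were not simulated, so recovery and false calls may differ in the real arrays. The share of changed probes was also far below the 24.7% and 21.7% that passed in the real female and male comparisons. The adjusted threshold depends on that share. In the female comparison 73% of changes of 1 log2 unit and 51% of changes of 0.5 were recovered, in the male comparison 78% and 55%, and in the interaction 66% and 27%, with 7, 7 and 5 false calls.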

Results

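Gene expression was measured in the cerebral cortex of mouse offspring to ask whether exposure to MDMA (3,4-methylenedioxymethamphetamine, an amphetamine that releases serotonin) before birth changes the transcripts of the brain. The 34 arrays comprised 7 female control, 8 female MDMA, 10 male control and 9 male MDMA samples. Probes with a signal-to-noise ratio of at least 3 made up 54.2% ± 2.9 (SD, n = 7) of all gene probes in female controls, 54.4% ± 1.8 (SD, n = 8) in female MDMA, 50.8% ± 1.3 (SD, n = 10) in male control and 56.5% ± 2.0 (SD, n = 9) in male MDMA offspring. Correlations between arrays ran from 0.89 to 0.99, and no 2 arrays held identical values. Values are log2 signals after quantile normalisation, fold changes are differences of group means on that scale, and adjusted p-values are limma's over 19022 probes. A symbol was available for 174 tested genes, so the genes named below are a small part of those that passed the tests.

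The first principal component, with 32.3% of the variance, placed female controls at -63.5 ± 16.4 (SD, n = 7), female MDMA at -14.8 ± 20.9 (SD, n = 8), male controls at 28.2 ± 16.1 (SD, n = 10) and male MDMA at 31.2 ± 8.7 (SD, n = 9). The second, with 8.8%, had a lower mean in MDMA than in control offspring of either sex, with no overlap of the female groups and some overlap of the male groups. Its means were 8.9 ± 10.6 in control and -23.6 ± 7.2 in MDMA females, and 22 ± 16.3 in control and -10.5 ± 7.7 in MDMA males (SD, with the same n). Female MDMA replicate 2 lay among the males on the first component, at 33.4, while the other female MDMA arrays lay between -35.7 and -11.8. Female controls rose on this component with replicate number at every step, from -89.4 in replicate 1 to -43.6 in replicate 7, towards the MDMA females. What the numbers stand for is not given.

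**Figure D1:**
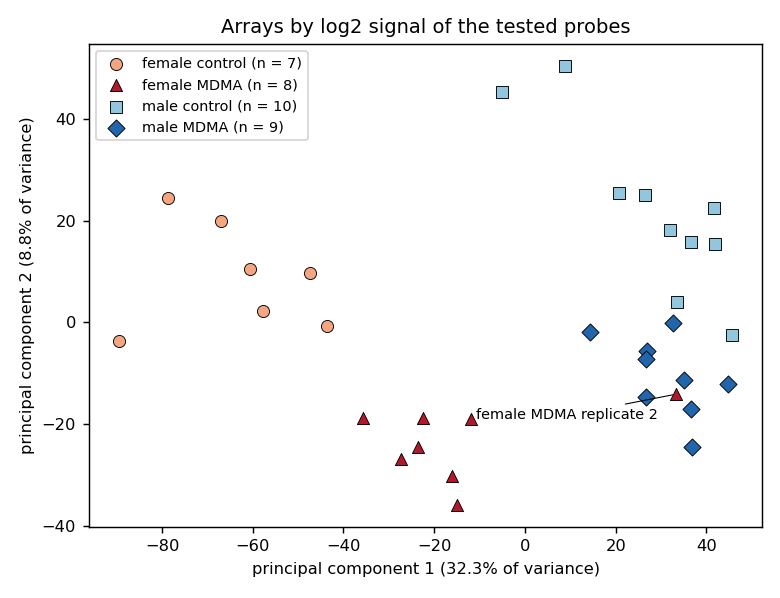
Each point is 1 of the 34 arrays, placed by the first (32.3% of variance) and second (8.8%) principal component of log2 signals, with colour and shape giving sex and treatment. Control and MDMA arrays of females separate along the second component, those of males overlap on it, and female MDMA replicate 2 sits at 33.4 on the first, among male arrays.

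In females, the secreted growth factor gene Mydgf rose 1.85-fold in MDMA offspring (log2 13.15 ± 0.24, SD, n = 7, in controls and 14.04 ± 0.15, SD, n = 8, with MDMA; limma adjusted p = 1.77e-07) and was above the control mean in 8 of 8 arrays. Nt5dc3 rose 1.80-fold (limma adjusted p = 2.09e-06) and Mpdu1, which acts in protein glycosylation, 1.47-fold (limma adjusted p = 5.65e-06), each in 8 of 8 arrays. Within the female controls, Nt5dc3 went from 13.31 in replicate 1 to 14.02 in replicate 7, and Mydgf from 12.99 to 13.57, towards the MDMA arrays. The lowest MDMA values were 14.31 for Nt5dc3 and 13.86 for Mydgf. Pou3f3, a POU transcription factor of cortical neurons, rose by 0.98 log2 units (SE 0.30), and Lhx2, a LIM homeobox factor of cortical patterning, by 0.39 (SE 0.10). Paqr9, a membrane receptor family gene, fell by 0.54 log2 units (SE 0.07, limma adjusted p = 1.52e-06), in 8 of 8 arrays. Sox11, a transcription factor of newborn neurons, fell by 0.58 (SE 0.16, limma adjusted p = 0.00968), and the forkhead gene Foxn3 fell by 0.39 (SE 0.09, limma adjusted p = 0.000918), each in 8 of 8 arrays. For Sox11, female control replicate 1 at 12.24 (others 11.50 to 11.72) raised the control mean. Female MDMA replicate 6, at 11.59, lay within the range of those other controls.

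Other female rises were Drg2 at 0.49, Gnas, the stimulatory G protein alpha subunit, at 0.41, and 4 dimmer genes. Those were the translation repressor Eif4ebp1 at 1.14, Cdc42ep1 at 1.02, Ldhal6b at 0.85 and Stat5a at 0.74. Eif4ebp1 and Ldhal6b reached the signal-to-noise minimum on 1 of 7 control and 4 of 8 MDMA arrays each, Stat5a on 1 and 3, Pou3f3 on 3 and 8, and Cdc42ep1 on 5 and 7, so their sizes lie near the floor. Other falls were Edar, the ectodysplasin receptor, at -0.63, Rtl8c at -0.47, Trim59 at -0.44, Zfp354b and Gpr119 at -0.41, Nat8f2 at -0.39, Nupr1l at -0.35 and the histone gene H2bc18 at -0.32. The calls of Eif4ebp1, Ldhal6b, Stat5a, Gpr119, Nat8f2 and Nupr1l lay near the threshold and were lost without 7, 7, 10, 10, 9 and 13 of the 34 arrays in turn. That of Cdc42ep1 was lost without female control replicate 2 (limma adjusted p = 0.0515). Those of Lhx2, Gnas and Drg2 were lost with median centring, and those of Eif4ebp1, Ldhal6b, Stat5a, Gpr119, Nat8f2 and Nupr1l under 3 of 9, 2 of 9, 4 of 9, 4 of 10, 2 of 10 and 3 of 10 processing alternatives. Over all probes, 4698 of 19022 (24.7%) passed in females, 2562 higher and 2136 lower with MDMA, and 884 of them changed at least 2-fold. Among named genes 15 rose and 21 fell. The largest rise and fall among unnamed probes above the signal-to-noise minimum on at least 1 array of each group were mCG142115.1 at 3.46 (SE 0.58) and a cDNA probe at -1.63 (SE 0.35). With median centring 7473 probes passed, 2210 higher and 5263 lower, and with spike-in components as covariates, an alternative chosen after seeing the data, 1557. With those components 16 of 22 named calls were lost, among them Pou3f3, Lhx2 and Sox11, and those of Mydgf, Nt5dc3, Mpdu1, Drg2, Paqr9 and Foxn3 were not.

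In males, Trim59 rose 1.67-fold with MDMA (log2 12.96 ± 0.36, SD, n = 10, in controls and 13.70 ± 0.21, SD, n = 9, with MDMA; limma adjusted p = 5.36e-05), in 9 of 9 arrays. The zinc finger genes Zfp945 and Zfp870 rose by 0.94 (SE 0.21) and 0.73 (SE 0.22), and Prr18 rose by 0.48 (SE 0.10), each in 9 of 9 arrays. The transcription factor gene Cebpb fell by 0.54 (SE 0.09, limma adjusted p = 0.000105), Fgf11, a fibroblast growth factor homologue of neurons, fell by 0.54 (SE 0.09, limma adjusted p = 9.02e-05), and Rnf112, a RING finger gene of neurons, fell by 0.54 (SE 0.09, limma adjusted p = 0.00014), each in 9 of 9 arrays. Mt3, the brain metallothionein that binds zinc, fell by 0.39 (SE 0.13, limma adjusted p = 0.0264). Hba-a1, an alpha globin of red blood cells, was lower too, at 18.48 ± 0.54 (SD, n = 9) with MDMA and 19.35 ± 0.55 (SD, n = 10) in controls (limma adjusted p = 0.00223), in 9 of 9 arrays, and this blood transcript moved alongside the genes above.

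Further male rises were Gpr27, an orphan receptor gene, at 0.99, Cdc42ep1 at 0.79, Tex46 at 0.72, 9130023H24Rik at 0.71 and A430057M04Rik at 0.63. Ldhal6b did not reach the signal-to-noise minimum on any of 10 male control arrays and reached it on 3 of 9 MDMA arrays. It was at least 2.57-fold higher with MDMA (limma adjusted p = 0.000241), taking for the controls the higher of the lowest signal among probes above that minimum and the probe's own, and for the brighter group, here and in similar cases, the mean over all its arrays, those under the minimum at their measured signal. This bound leaves out sampling error (SE 0.26 log2 units at the measured signals). Further falls were the olfactory receptor genes Olfr347 at -1.18 and Olfr1189 at -0.60, Tcim at -0.63, Gpr119 at -0.53, Cd99 at -0.49 and Mapk1ip1 at -0.43. Gpr27 reached the minimum on 3 of 10 control and 4 of 9 MDMA arrays, Olfr347 on 5 and 1, Olfr1189 on 8 and 7, 9130023H24Rik on 4 and 9, A430057M04Rik, Tex46 and Zfp870 on 6 and 9, and Zfp945 and Cdc42ep1 on 7 and 9. The calls of Gpr27, Cdc42ep1, Tex46, A430057M04Rik and Olfr347 were lost without 13, 21, 18, 11 and 11 of the 34 arrays in turn, and that of Mt3 without male MDMA replicate 7 (limma adjusted p = 0.0587) and under 4 of 10 processing alternatives. The calls of Gpr27, Cdc42ep1, Tex46, A430057M04Rik and Olfr347 were lost under 4, 5, 4, 4 and 5 of 9, that of Ldhal6b with the authors' table, and that of Zfp870 with only the male arrays fitted. Over all probes 4127 (21.7%) passed in males, 2239 higher and 1888 lower, with 195 of them changed at least 2-fold, and among named genes 25 rose and 20 fell. The share of probes above the signal-to-noise minimum differed with treatment in males, lying between 48.9% and 52.9% on control arrays and between 53.1% and 59.5% on MDMA arrays, with no overlap, and the median signal ran from 993 to 1560 and from 1214 to 2344. The largest changes among unnamed probes above the signal-to-noise minimum on at least 1 array of each group were mCG14564.1 at 2.08 (SE 0.23) and mCG22246.1 at -1.99 (SE 0.59). With median centring 6886 probes passed, 6237 higher and 649 lower, and with spike-in components as covariates 1752. With those components 9 of 21 named calls were lost, those of Hba-a1, Mt3, Zfp870, Tcim, Olfr347, Olfr1189, Cdc42ep1, Tex46 and 9130023H24Rik.

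**Figure D2:**
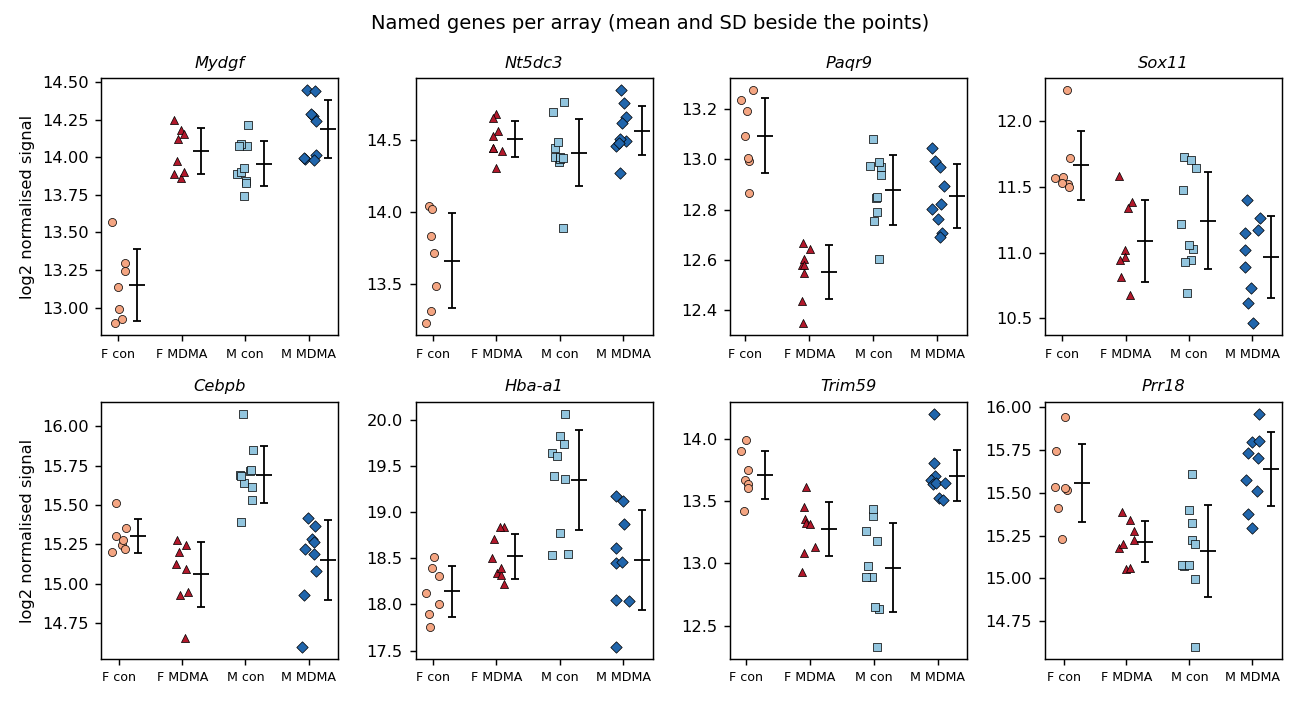
Log2 normalised signal of 8 named genes on each array, by sex and treatment (7 female control, 8 female MDMA, 10 male control, 9 male MDMA), with mean and SD beside the points. Mydgf, Nt5dc3, Paqr9 and Sox11 changed with MDMA in females, Cebpb and Hba-a1 fell in males, and Trim59 and Prr18 moved in opposite directions in the sexes.

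Of the 40 gene lists, 10 had a tested member, 11 genes in all. All but the histones had 1 tested member, for which the p adjusted over the list alone is the unadjusted p. Adjusted over the list alone in this sense, the female effect passed for Lhx2 (cortical layer markers), Sox11 (proliferation), H2bc18 of the 2 histone genes and the splicing gene Sf3b5, which at -0.20 (SE 0.09) did not pass over all probes (limma adjusted p = 0.0877). The male effect passed for Hba-a1 (blood) and Mt3 (oxidative stress). The synaptic gene Snap25 stood at -0.96 (SE 0.50) in females and 0.35 (SE 0.44) in males, and the immediate-early gene Jun at 0.04 (SE 0.14) and -0.19 (SE 0.13); these did not pass in either sex. The potassium channel subunit Kcne4 stood at 0.63 (SE 0.38) and -0.32 (SE 0.33), and Ramp3 at -0.10 (SE 0.09) and -0.08 (SE 0.08), neither past the threshold.

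Averaged over the sexes, MDMA offspring had more Cdc42ep1 (log2 fold change 0.90, SE 0.22), Pou3f3 (0.69, SE 0.20), Mydgf (0.56, SE 0.06) and Mpdu1 (0.46, SE 0.06; limma adjusted p = 5.61e-07), and less Gpr119 (-0.47, SE 0.10), Sox11 (-0.43, SE 0.11) and Fgf11 (-0.41, SE 0.07). Other rises were Ldhal6b, below the signal-to-noise minimum on all male control arrays, Wdfy1 at 0.67 (above the minimum on 4 and 5 female and 4 and 8 male arrays, control before MDMA), Stat5a at 0.61, Nt5dc3 at 0.50, Zfp870 at 0.44 and Drg2 at 0.40. Other falls were Olfr1189 at -0.40, Cebpb at -0.39, the Ras-related gene Rasd1 at -0.34, Rtl8c at -0.30, Paqr9 at -0.29, Mapk1ip1 at -0.27 and Psme3, a proteasome activator subunit, at -0.25. The Zfp870 call was lost without 16 of the 34 arrays in turn, and that of Olfr1189 without female control replicate 1 (limma adjusted p = 0.0505). Calls were also lost under processing alternatives, 3 of 8 for Zfp870, 1 of 8 for Olfr1189 and Stat5a, 2 of 9 for Psme3 and 1 of 9 for Rasd1. In all, 5295 probes (27.8%) passed, 2880 higher and 2415 lower, and among named genes 15 rose and 24 fell. With median centring the split of the calls was 3100 higher and 1523 lower, and with spike-in components as covariates 1433 probes passed and 12 of 20 named calls were lost, among them Cdc42ep1, Pou3f3 and Gpr119. An averaged change need not be shared by the sexes. Of the genes named for the average, Ldhal6b, Cdc42ep1, Mpdu1, Gpr119 and Fgf11 passed in both sexes, and the others in only 1 or in neither. Paqr9 stood at -0.03 and Nt5dc3 at 0.15 in males, and Psme3 at -0.09 in females.

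The female and male effects were weakly correlated across probes (Pearson 0.18, Spearman 0.13). Among the 100 regroupings of the arrays, 16 gave a Pearson value as far from 0, the observed one included, and the others ran from -0.34 to 0.37, so the correlation was not beyond chance. The Pearson value was 0.10 without male control replicate 10 and 0.09 with array weights. Probes called in both sexes numbered 360 higher and 354 lower in both, against 301.6 and 212 for independent lists. In opposite directions they numbered 149 and 246, against 254.3 and 251.4. Of 12 named genes called in both sexes, 7 moved the same way: Ldhal6b, Cdc42ep1, Mpdu1 and Gnas rose, and Gpr119, Fgf11 and Hsd17b10 fell. The 5 others, Trim59, Prr18, Nupr1l, Otub1 and Lgals7, moved in opposite directions.

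**Figure D3:**
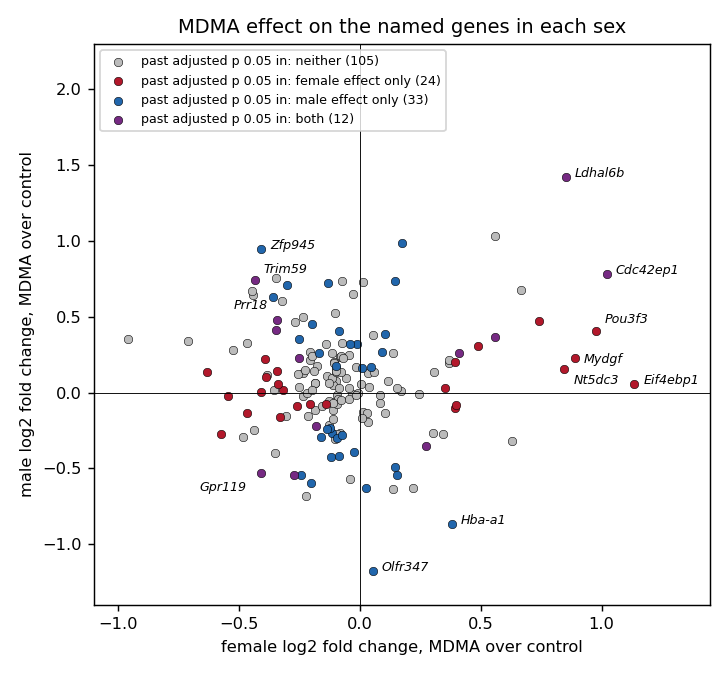
Log2 fold change of MDMA over control in females (horizontal axis) and males (vertical axis) for the 174 named genes, coloured by the sexes in which limma's adjusted p was under 0.05. The 12 genes past it in both sexes comprise 7 with the same direction and 5 with opposite directions.

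The MDMA effect differed between the sexes for 4409 probes (23.2%), the female effect being higher for 2055 and lower for 2354. The set of 20 arrays that shared on/off probes held all 19 male arrays but only 1 of the female arrays. A difference in the MDMA effect between the sexes therefore cannot be told apart from one between array sets. Of 35 named genes past the threshold, it was higher for 10 and lower for 25. Trim59 differed by -1.18 (SE 0.18, limma adjusted p = 3.61e-05), falling in females and rising in males, and Prr18 by -0.82 (SE 0.15, limma adjusted p = 0.000303) likewise. The other 2 Prr18 probes stood at -0.31 and -0.20 in females, neither past the threshold, and at 0.29 and 0.41 in males, of which the second passed. Mydgf differed by 0.66 (SE 0.13) and Nt5dc3 by 0.69 (SE 0.16), and Lhx2 by 0.50 (SE 0.14). The blood transcript Hba-a1 differed by 1.25 (SE 0.30). Rnf112, Cd99, Otub1, Tspyl2, Pdxp and Nt5m had a higher effect in females by 0.69, 0.63, 0.63, 0.48, 0.32 and 0.21. Among the largest differences the other way, Zfp945, 9130023H24Rik, A430057M04Rik, Edar, Nupr1l, Bhlha9 and Nat8f2 had a lower one, by -1.35, -1.01, -0.99, -0.77, -0.76, -0.65 and -0.62. The call of A430057M04Rik was lost without 4 of the 34 arrays in turn, and those of Edar and Bhlha9 without female control replicates 2 and 1 (limma adjusted p = 0.0546 and 0.058). With median centring 8236 probes differed, 1105 higher and 7131 lower, and the calls of Rnf112, Nt5dc3, Cd99, Otub1, Lhx2, Tspyl2, Pdxp and Nt5m were lost, the last 2 turning sign. Those of Nt5m, A430057M04Rik and Bhlha9 were lost with no filter on dim probes, and that of A430057M04Rik also with the authors' table. With spike-in components as covariates 2076 probes differed and 7 of 19 named calls were lost, those of Lhx2, Pdxp, Nt5m, Edar, Nupr1l, Bhlha9 and Nat8f2.

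The other probe of Cebpb, which is the dimmer, stood at 0.73 in females (limma adjusted p = 0.0495) and 0.08 in males, and so disagreed with the brighter one at -0.24 and -0.54. Quantile normalisation left the median of all tested probes at -0.08 in females and 0.06 in males, and median centring at -0.19 and 0.21. For the interaction these medians were -0.09 and -0.34, and for control females against males 0.11 and 0.38. Directions of single genes are therefore relative to the quantile-normalised distribution, and the balance of higher and lower calls depended on the scaling. It also depended on the probe filter and array weights. The share of higher calls in females was 54.5%, but 46.5% with the signal-to-noise minimum on all arrays and 47.6% with array weights. In males it was 54.3%, but 47.4% with no filter on dim probes.

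Control females and males differed at 10052 probes (52.8%), 5944 higher and 4108 lower in females, and 72 named genes were higher and 18 lower. Lhx2 was lower in females by 0.93 log2 units, at 14.24 ± 0.26 (SD, n = 7) against 15.17 ± 0.18 (SD, n = 10; limma adjusted p = 5.61e-09). Hba-a1 was lower at 18.14 ± 0.28 (SD, n = 7) against 19.35 ± 0.55 (SD, n = 10; limma adjusted p = 2.28e-05), as were Mydgf at -0.81, Pou3f3 at -0.77 and Nt5dc3 at -0.75. Fmr1nb at 1.54, 9130023H24Rik at 1.26, Tex46 at 1.11 and Dcaf12l2 at 1.09 were higher. AY074887 was not above the signal-to-noise minimum on any of 10 male control arrays, and 5 of 7 female control arrays were above it. At the measured signals, which the floor did not change, it was 2.3-fold higher in females (SE 0.37 log2 units, limma adjusted p = 0.00808). Among list members, H2bc18 stood at 0.46, Sox11 at 0.42, H2bc13 at 0.23 and Mt3 at -0.34, the last turning sign with median centring. The Sox11 call was lost without female control replicate 1 (limma adjusted p = 0.0828), and those of H2bc13, Mt3 and Pou3f3 without 25, 8 and 5 of the 34 arrays in turn. Under processing alternatives the call of AY074887 was lost in 2 of 9, H2bc13 in 2 of 10, Mt3 in 3 of 10 and Pou3f3 in 1 of 9. With a covariate for a set of arrays that shared on/off probes, chosen after seeing the data, 14 of 14 named calls were lost. Of the 10 male control arrays, Dcaf12l2 was above the minimum on 5, 9130023H24Rik on 4, Tex46 on 6 and Fmr1nb on 8, and Pou3f3 was above it on 3 of 7 female control arrays.

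MDMA females and males differed at 4121 probes (21.7%), 2143 higher and 1978 lower in females, and 21 named genes were higher and 8 lower. Flcn, the tumour suppressor folliculin, was higher in females by 0.77 (SE 0.10, limma adjusted p = 1.59e-06), Olfr1189 by 0.94 (SE 0.19), the oocyte kinase gene Mos by 1.12 (SE 0.30) and the chemokine Ccl21a by 1.01 (SE 0.27). Fpr-rs6 was not above the signal-to-noise minimum on any of 9 male MDMA arrays and was at least 2.23-fold higher in females, where 3 of 8 arrays were above it (limma adjusted p = 0.017). That bound leaves out sampling error (SE 0.37 log2 units at the measured signals). Mos reached the minimum on 6 of 8 female and 2 of 9 male arrays, Ccl21a on 7 and 1, and Olfr1189 on 7 and 7. Rsph3a, the RNA demethylase gene Alkbh5, Lhx2, Trim59 and Prr18 were lower in females, at -0.55, -0.52, -0.43, -0.43 and -0.42. The call of Fpr-rs6 was lost without female MDMA replicate 8 (limma adjusted p = 0.0506), and those of Fpr-rs6 and Ccl21a with the authors' table. With the same covariate 10 of 10 named calls were lost, and Flcn, Rsph3a and Lhx2 turned to small values of the other sign. That contrast then rests on 1 female array, so lost calls and signs near 0 show little.

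Both sex comparisons carried a further difference between arrays. On 28 probes, 17 high and 11 low by at least 2 log2 units, all 19 male arrays and female MDMA replicate 2 stood apart from the other 14 female arrays. With this set of 20 arrays as a covariate, chosen after seeing the data, 438 probes differed between control sexes and 8 between MDMA sexes, and among MDMA arrays of that set (1 female, 9 male) 16. The lone female array was assumed to vary like the others, few calls can pass in such a fit, and sex and array set cannot be told apart except through that 1 array. For the MDMA effects the covariate tests little, as all male arrays lie in 1 set and all but 1 female array in the other. It gave 4377 probes for the female and 4375 for the male MDMA effect. Leaving out female MDMA replicate 2 gave 4377 and 4374.

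**Figure D4:**
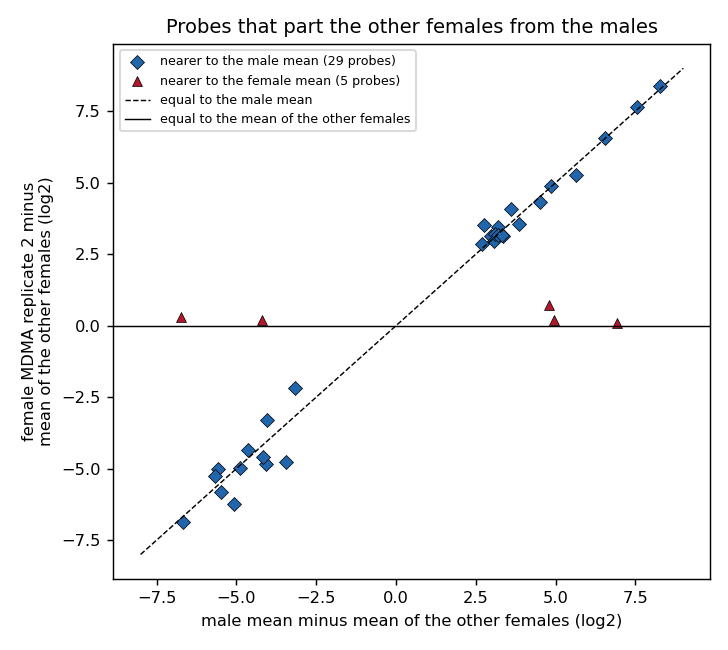
For 34 probes that part the other 14 females from the 19 males by at least 2 log2 units, the male mean (horizontal axis) and female MDMA replicate 2 (vertical axis) are drawn relative to the mean of the other females. On 29 probes the array lay nearer to the male mean (dashed line), and on 5 nearer to the females (solid line).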

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

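The tests of a wrong sex label, of a sex difference on the on/off probes and of the array set in the sex comparison, and the fits with the array set or spike-in components as covariates, were chosen only after the result was seen or the data examined.

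The MDMA effect differed between the sexes, by the interaction test, at 4409 probes. Of 35 named genes past the threshold, the female effect was higher for 10 and lower for 25. It exceeded the male effect for Hba-a1 by 1.25, Rnf112 by 0.69, Nt5dc3 by 0.69, Mydgf by 0.66, Cd99 by 0.63, Otub1 by 0.63, Lhx2 by 0.50, Tspyl2 by 0.48, Pdxp by 0.32 and Nt5m by 0.21 log2 units. Among the largest differences the other way, it lay below the male effect for Zfp945 (-1.35), Trim59 (-1.18), 9130023H24Rik (-1.01), A430057M04Rik (-0.99), Prr18 (-0.82), Edar (-0.77), Nupr1l (-0.76), Bhlha9 (-0.65) and Nat8f2 (-0.62). With median centring the calls of Rnf112, Nt5dc3, Cd99, Otub1, Lhx2, Tspyl2, Pdxp and Nt5m were lost, Pdxp and Nt5m turning sign, and with no filter on dim probes those of Nt5m, A430057M04Rik and Bhlha9. Of 100 splits of the arrays within each sex, 1 gave as many probes, the real one, and the highest of the others gave 1196. Such splits mix control and MDMA arrays, so they stand for no MDMA effect in either sex. They do not stand for equal MDMA effects in both sexes. Whether the difference between the sexes is beyond chance therefore cannot be decided from them. The splits cannot tell sex from array set, as the males and all but 1 female array lie in different sets.

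Single arrays stood far from the rest of their group in 19 of 236 groups of values looked at. The rule was Dixon's outlier test, at critical values that by design flag about 1 in 20 groups of normal values. The groups share arrays and so are not independent. Female MDMA replicate 2 was low for Drg2 (13.57, others 14.50 to 14.81), Flcn (15.45, others 16.14 to 16.63) and Fmr1nb (10.62, others 11.71 to 12.09), and high for Lhx2 (15.10, others 14.46 to 14.64) and on the first principal component (33.4). Male control replicate 10 was low for Nt5dc3 (13.89) and Pou3f3 (8.63) and high for Psme3 (15.06). Female control replicate 1 was high for Fgf11 (13.90) and Sox11 (12.24), and female control replicate 7 for Nt5m (15.67). The rest were 9130023H24Rik in female MDMA replicate 4 (10.65), Mos in female MDMA replicate 7 (8.82), Tcim in female MDMA replicate 6 (11.55), Tex46 in male control replicate 6 (8.92), Zfp945 in male control replicate 7 (8.20), Ldhal6b in male MDMA replicate 1 (8.43), Mt3 in male MDMA replicate 7 (15.73) and Trim59 in male MDMA replicate 9 (14.20).

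Female MDMA replicate 2 shared on/off probes with the males. A wrong sex label would put it with the males on every probe that parts the sexes, but on 5 of 34 such probes it lay at the female level. It lay at the male level on the other 29, but 28 of these are the probes on which the pattern was seen, so this count adds little against a sex difference between animals. On 14 negative and manufacturing control probes, which are not aimed at mouse genes, its place between the other female MDMA arrays (0) and the male MDMA arrays (1) was 0.999, inside the range of the males (0.866 to 1.08) and outside that of the other females (-0.102 to 0.21), which a sex difference between animals would not give. A candidate explanation is therefore an array or hybridization set shared with the males.

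That set could also account for much of the sex difference, in controls, where with it as a covariate the median ratio of adjusted to unadjusted differences was 0.578 and 438 probes passed, 376 of them among the 10052 and in the same direction, and in MDMA offspring, where the ratio was 0.103 and 8 probes passed. The covariate rests on 1 female array, whose own deviation enters every adjusted difference, so the set and sex cannot be told apart, and a biological sex difference stays open. Of 100 splits of the arrays, the real one included, 1 gave as many probes, the real one with 10052, against 1385 for the highest other, and in MDMA offspring 1 gave 4121 or more, against 781, which excludes chance but not the array set.

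The MDMA effects were set against a difference at the labelling step. In males the IVT controls stood higher over the hybridization controls with MDMA, by 0.38 log2 units (exact permutation test, two-sided, n = 9 and 10, p = 0.00848, adjusted over 9 tests 0.0254), and in females by 0.08 (exact p = 0.685). With spike-in components as covariates the called fold changes kept a median ratio of 0.889 in females (0.768 to 0.967 without single arrays) and 0.938 in males (0.91 to 0.96), which argues against the labelling difference, so far as the spike-ins follow it, as the whole cause. The counts fell to 1557 and 1752 as the median standard error grew from 0.136 to 0.192 and from 0.121 to 0.15. The median size of the called changes went from 0.47 to 0.43 and from 0.37 to 0.35. Standard errors grow in such a fit where the components run along with treatment. A labelling difference as a part of the cause therefore stays open. Of 100 splits each, 1 gave as many probes as the real one in females (4698, highest other 1131), males (4127, 766) and the average of both (5295, 1974), which excludes chance, but a litter or processing day shared by a group stays open and was not tested, as does MDMA itself. The controls were labelled non-treated. If they got no saline by mouth, the dosing itself cannot be told apart from MDMA. The shift of female controls with replicate number was not tested as a cause either.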

How the results depend on the processing

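Alternatives with covariates or within an array set were chosen after seeing the data, and the rest before. Among the latter, counts stayed within 1.5 times except with median centring, where the female effect had 7473 probes, the male 6886 and the interaction 8236, and with array weights, where the sex difference in MDMA offspring had 6189. The cause was not tested. The shares of higher calls moved with median centring from 54.5% to 29.6% in females, 54.3% to 90.6% in males, 54.4% to 67.1% on average, 46.6% to 13.4% for the interaction and 59.1% to 79.1% for control sexes, as the medians of all probes shifted. With spike-in components as covariates the female effect had 1557 probes, the male 1752, the average 1433 and the interaction 2076, with larger standard errors. With the array set as a covariate the sex difference had 438 probes in controls and 8 in MDMA offspring, and within that set 16 in MDMA offspring, where the lone female array is assumed to vary like the males. Leaving out each array in turn gave 3920 to 4955 probes for the female effect, 3576 to 4374 for the male, 4784 to 5464 for the average, 3687 to 4882 for the interaction, 9090 to 10288 for control sexes and 3185 to 5269 for MDMA sexes, the highest without female MDMA replicate 2. The correlation of the effects ran from 0.10 to 0.23 without single arrays and from 0.09 to 0.21 under the other alternatives set beforehand, and no alternative moved it by more than its jackknife error of 0.14. The regroupings gave 16 values of 100 as far from 0 as 0.1818, with 0.3724 the farthest of the others, so chance is not excluded. Signs turned with median centring for Pdxp (-0.13) and Nt5m (-0.25) in the interaction and Mt3 (0.19) between control sexes, with the array set as a covariate for H2bc13 between control sexes (-0.01), and for Flcn (-0.0798), Rsph3a (0.0517) and Lhx2 (0.0388) between MDMA sexes, with the same 3 values within the set. Of 106 results for named genes, 68 kept their call and direction under every alternative set beforehand that gave a value, single arrays aside, 38 lost it under at least 1, and 83 kept it without each single array. With alternatives added later, spike-in components left 38 of these calls and ended 44, and the array set as a covariate left 77, ended 25 and turned 4, including 14 of 14 between control sexes and 10 of 10 between MDMA sexes. The 77 were all calls of an MDMA effect or the interaction, for which the array set covariate acts almost as leaving out female MDMA replicate 2. Same-numbered control and MDMA samples of a sex did not deviate together (correlations -0.14 to 0.08 in 7 female and -0.13 to 0.16 in 9 male pairs, of which 1 and 2 correlated best with their own number). No pairing by number was thus seen within a sex, though a weak one could be missed. Same-numbered females and males were not compared. The replicate block gave 4523 female, 3850 male, 4971 average and 4540 interaction calls, 9964 between control sexes and 3865 between MDMA sexes. The list tests and the slide block gave no value, for lack of members and of slide labels. Signal over background limits the dim genes, as 30.6% of spots lay at the floor.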

Other observations

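The camera tests of 4 groups were chosen after the names, but not the values, had been seen. The 7 groups formed from symbols alone, after the names were seen and before any test, gave no shift past the threshold in either sex where tested. Of 22 neuronal and neurodevelopmental genes, 2 rose and 2 fell in females and 2 rose and 3 fell in males (camera adjusted p = 0.869 and 0.465). Of 19 genes of the Smith-Magenis interval, a gene-dense stretch well represented among the named probes, 1 rose in females, and 1 rose and 2 fell in males (camera adjusted p = 0.869 and 0.465). Of 11 immune genes 1 rose in females, and 1 rose and 1 fell in males (camera adjusted p = 0.869 and 0.465). Of 6 olfactory, vomeronasal and taste receptor genes 2, Olfr347 and Olfr1189, fell in males, and the group had a median of -0.45 (camera p = 0.044, adjusted p = 0.176, and 0.204 with an estimated correlation). The 4 tested genes of the Prader-Willi and Angelman region, the maternally or paternally expressed Ube3a, Ndn, Mkrn3 and Peg12, held no call in either sex. The 2 keratin-associated genes held none either, and of the stress factors Jun and Cebpb the latter fell in males.

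The spike-in controls differed between the female control and the male control arrays. RT and IVT controls are added and are not RNA of the animals, so their difference points to the handling of the samples or arrays. It was not tested as a cause of the 10052 probes that differed between control sexes. The RT controls stood lower against the IVT controls in female than in male controls, by -0.65 log2 units (exact permutation test, two-sided, n = 7 and 10, p = 0.000103, adjusted over 9 tests 0.000927). The hybridization controls stood 0.45 higher over the array median (exact permutation test, two-sided, n = 7 and 10, p = 0.000206, adjusted 0.000927). The IVT controls stood 0.49 higher over the hybridization controls (exact permutation test, two-sided, n = 7 and 10, p = 0.0119, adjusted 0.0268).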
